A study of Mus musculus with 18 samples.

How the data were processed

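RNA was sequenced from mouse oligodendrocyte progenitor cells (OPCs) made from epiblast stem cells. The cells carried a CRISPR control or a CRISPR edit of Vhl. Per the labels' protocols, they were grown with the growth factors Fgf2 and Pdgfa, RNA was extracted with TRIzol, and Novogene prepared and sequenced the libraries. The first experiment holds untreated control and Vhl cells. In the second, control and Vhl cells received medium with DMSO or with 300 nM of AZD8330, an inhibitor of the kinases MEK1 and MEK2, for 14 hours before lysis. Each of the 6 groups has 3 libraries, lettered A to C, which makes 18 libraries. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which can be technical. The library kit, its strandedness, the read length and the gene annotation of the authors are not given in the sources used here.

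The authors deposited 2 tables, with 54279 rows each, for the 6 untreated libraries and the 12 libraries of the drug experiment. Per the submitters' processing notes, Salmon 0.14.1 was used with the mouse build mm10; how transcript values were combined into gene values is not given in the sources used here. The deposited tables are named as TPM, but the values are estimated counts: column totals lie between 12391077 and 21160250 and differ between libraries, whereas TPM sums to the same total in every library. Of the values above 0, 57.7% in the untreated table and 58.8% in the drug table are whole within 0.001. The test fixed before the data were examined, limma on log2(TPM + 1), assumed TPM. Because the deposited values are estimated counts, they were rounded to whole numbers and tested with the quasi-likelihood test of edgeR instead, and the limma test on log2(CPM + 1) became an alternative. The untreated table also holds 2 mean columns made by the authors, which entered no comparison. A date stands in 26 rows of each table in place of a gene symbol, as spreadsheet programs produce. These rows were kept in the fits and are not named, and neither is a row of the drug table named only with a digit. Of all rows, 98.37% have a name that is in GENCODE M21, the annotation of GRCm38 (mm10) used here for positions, which are 1-based. No pair of libraries had identical values.

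The 2 tables were fitted separately and never combined. Genes with a mean of at least 1 CPM over the libraries of a table were tested, which left 13569 genes in the untreated table and 13460 in the drug table. Library sizes were scaled with TMM. Values in CPM, counts relative to the scaled library total, are given as mean ± SD over 3 libraries, and log2 changes are given with their standard error (SE). The 2 untreated groups were fitted together, and the 4 groups of the drug experiment shared a single fit, from which the 5 contrasts of that experiment were taken. P-values were adjusted over all tested genes with the Benjamini-Hochberg method, separately per comparison, and 0.05 was the threshold. A rise or fall means an adjusted p under that threshold. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9.

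Before the data were examined, 24 gene lists were fixed from textbook knowledge: glycolysis, other hypoxia response genes, HIF pathway components, OPC identity, oligodendrocyte maturation, MEK/ERK output, S phase, G2 and M phase, cholesterol synthesis, interferon response and antigen presentation, unfolded protein and integrated stress response, p53 response, Wnt targets, Notch targets, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, and markers of neurons, astrocytes, neural progenitors, pluripotent cells, mesenchymal cells, microglia, endothelial cells, and Schwann and neural crest cells. Lists with at least 5 tested members were tested with camera of limma at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. The adjusted p with an estimated correlation is given beside each call that it ends. 20 lists were tested. None of 9 microglia markers was tested in either table, and the pluripotency list had 3 tested members in the drug table and 2 in the untreated table, the endothelial list 2 and the Schwann and neural crest list 3, too few for a test. The Egln1 and Egln3 genes stand on both the hypoxia list and the HIF pathway list, and Slc2a1 counts under glycolysis.

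The rule for named genes was also fixed beforehand, in terms of log2(TPM + 1) and TPM. It was applied here to edgeR's log2 changes and to CPM, which ranks genes near 0 higher than log2(TPM + 1) would. It takes, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among changed genes whose groups do not overlap and whose higher group reaches 5 CPM (5 and 5 for the difference of drug effects, without the overlap condition). It adds up to 4 members of each list with the smallest p-values, and 23 fixed genes. Unnamed gene models and pseudogene symbols were left out. 2 of the fixed genes, Ascl2 and Dlx3, come from knowledge of the study, which chose them on its own samples. Of the fixed genes, Pdk1 is not analysed in the drug table, and Epas1 is listed at 0 in all 18 libraries. Where the lower group of a gene holds 1 to 3 counts in total, its ratio is given with a 95% counting interval from the exact binomial method. Where that group holds none, a lower bound against 3 counts over the group is given. Such intervals and bounds cover counting error only.

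Values of some widely expressed genes are low for what is known of them: Actb held 4001 counts over the 12 drug libraries, and 104 genes differed over 10 times between libraries of a group. The values may therefore not cover all reads of a gene. Named genes affected by such jumps are marked where they are printed. Genes that share sequence with others are uncertain too: at least 20% of the 31-base words in the transcripts of Mif, Gapdh, Pgam1, Loxl2, Phyhd1, Etv5, Pcna, Cycs, Uhrf1, H2-K1, H2-D1 and most named mitochondrially encoded genes also occur in another annotated gene.

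The edgeR and camera steps were tested on simulated counts drawn from the means and library sizes of the real libraries, with 100 genes changed at each planted size. For the untreated comparison (13349 genes in that step) edgeR recovered 1% of planted log2 changes of 1 and 44% of those of 2, and 1 of 46 calls was false. For Vhl against control in DMSO (13329 genes) the shares were 64% and 91%, and 12 of 167 calls were false (7.19%), above the nominal level. For the difference of drug effects (13329 genes) they were 53% and 82%, and 7 of 142 calls were false (4.93%). Camera called a list of planted rises and 0 of the lists without planted changes in each of the 3. The simulated genes were drawn independently, so this does not test camera where genes of a list are correlated.

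Alternatives fixed beforehand were a smaller pseudocount and quantile normalization (both in limma, where they belong), no filter on low values, a minimum of 5 CPM, median-of-ratios scaling, no abundance trend, a fit of the 2 compared groups alone, the replicate letter as a block, leaving out each library in turn, and an estimated correlation for the lists. Chosen after the data had been seen were limma with pseudocount 1, DESeq2, total-count scaling, leaving out mitochondrially encoded genes and CT010467.1, leaving out both untreated A libraries, and a comparison of AZD8330-treated Vhl cells with DMSO-treated control cells. The values of some genes that entered the tests and lists are not reported here.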

Results

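Mouse oligodendrocyte progenitor cells (OPCs), the dividing precursors of the myelin-forming cells of the central nervous system, were compared with and without a CRISPR edit of Vhl. The VHL protein marks the alpha subunits of hypoxia-inducible factor (HIF) for degradation when oxygen is present, so its loss is known to raise HIF target genes in normal oxygen. 18 libraries form 6 groups of 3: untreated control and Vhl cells, and control and Vhl cells given DMSO or the MEK inhibitor AZD8330. Untreated libraries held between 14594148 and 21160250 estimated counts each and those of the drug experiment between 12391077 and 16349676. Expression values below are mean CPM ± SD over n = 3 libraries, and log2 changes carry their SE. Untreated libraries spread far more within groups (common edgeR dispersion 0.144) than those of the drug experiment (0.0161). In the untreated set the A libraries of the control and Vhl groups stood apart from B and C: Sox10 was 526.9 CPM in control A against 88.05 and 87.76 in B and C, and 327.1 in Vhl A against 15.32 and 16.02. CT010467.1 took 3.72% of the counts of untreated control A, the largest share of any library, where the smallest was 0.257%.

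Vhl mRNA was lower in each Vhl library than in each control library of the same treatment. In untreated cells it was 116.9, 121.1 and 125.4 CPM in controls A, B and C and 87.31, 90.19 and 74.14 CPM in Vhl A, B and C. The means of 121.1 ± 4.26 and 83.88 ± 8.56 (log2 −0.53 ± 0.16) did not pass as different (adjusted p = 0.357, edgeR's quasi-likelihood test). In DMSO it was 108.8, 107.1 and 102.3 CPM in controls and 90.04, 93.17 and 94.08 CPM in Vhl cells, a fall of log2 −0.20 ± 0.05 (adjusted p = 0.00777, edgeR's quasi-likelihood test). In AZD8330 it was 139.8, 136.7 and 138.3 CPM in controls and 103.7, 104.7 and 92.02 CPM in Vhl cells, a fall of log2 −0.46 ± 0.05 (adjusted p = 1.01e-05, edgeR's quasi-likelihood test). The part of Vhl that was edited is not given in the sources used here, and an edit that breaks the protein need not lower the mRNA. Vhl lies on chromosome 6 from 113623959 to 113631633 on the plus strand (GRCm38, GENCODE M21).

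The untreated comparison asked what loss of VHL changed in OPCs without any drug. 2 genes of the hypoxia response rose: Mif, which encodes a cytokine, from 54.74 ± 1.65 to 367.2 ± 46.6 CPM (log2 2.75 ± 0.18), and Fam162a, a nuclear gene that responds to HIF and encodes a mitochondrial protein, from 16.92 ± 0.925 to 103.8 ± 11.2 CPM (log2 2.62 ± 0.17). Each had an adjusted p of 0.00789 in edgeR's quasi-likelihood test. No gene fell. For Mif, 34.3% of the 31-base words occur in another gene too. Other hypoxia genes were much higher in Vhl cells but varied too widely to pass. Bnip3, a receptor for the removal of mitochondria, was 17.91 ± 1.12 CPM in control and 396.9 ± 205 CPM in Vhl cells (adjusted p = 0.0837, edgeR's quasi-likelihood test). The angiogenic factor Vegfa was 7.01 ± 1.14 and 363.7 ± 305 CPM (adjusted p = 0.137, edgeR's quasi-likelihood test). The glucose transporter gene Slc2a1 was 50.81 ± 4.13 and 278.5 ± 151 CPM (adjusted p = 0.16, edgeR's quasi-likelihood test). Pdk1, whose product slows the entry of pyruvate into mitochondria, was 37.47 ± 6.12 and 593.6 ± 394 CPM (adjusted p = 0.125, edgeR's quasi-likelihood test).

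**Figure D1:**
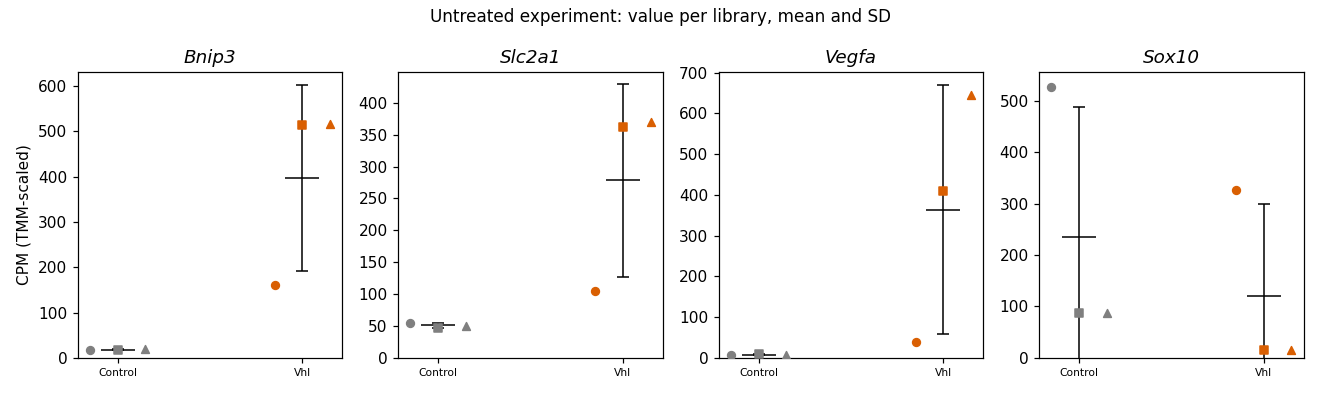
Bnip3, Slc2a1, Vegfa and Sox10 in CPM (vertical axes) per untreated library, with circles for A, squares for B and triangles for C. Bars show mean and SD, those of Sox10 are cropped at 0, and the A library of the Vhl group lies nearest the controls for the hypoxia genes.

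Vhl A carried most of that spread. It held 38.81 CPM of Vegfa against 408.4 and 644 in B and C, 160.1 CPM of Bnip3 against 513.7 and 517, and 2667 CPM of Gapdh against 6107 and 9274. Leaving out each library in turn was planned, and without Vhl A 439 genes changed (308 rose, 131 fell). Vegfa (log2 6.23), Bnip3 (log2 4.85), Slc2a1 (log2 2.85), Pdk1 (log2 4.45), Ascl2 (log2 6.33) and Dlx3 (log2 8.90) then rose. That run is set apart here because Vhl A was weak in these same genes. Its calls on them are therefore not separate evidence that they rise. Sox10, the transcription factor needed for oligodendrocyte differentiation, did not pass with all libraries (log2 −0.97 ± 1.29, adjusted p = 0.886, edgeR's quasi-likelihood test) or without Vhl A. Conversely 0 genes passed without control A, B or C or without Vhl B, so the Mif and Fam162a calls are lost there.

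By list, glycolysis was higher in Vhl cells (camera adjusted p = 1.49e-26; 0.213 with an estimated correlation), with 0 of 20 genes called over all genes and 15 rising when adjusted over the list alone. Among them the enzyme genes Tpi1 and Pfkl went from 84.34 ± 10.5 to 994.2 ± 397 and from 76.58 ± 10.7 to 870.3 ± 504 CPM. The other hypoxia genes were higher too (camera adjusted p = 1.18e-55; 0.213 with an estimated correlation), with 2 of 31 called and 25 rising when adjusted over the list alone. Oligodendrocyte maturation was lower (camera adjusted p = 0.000479; 0.507 with an estimated correlation; 0.0922 without control A), with 0 of 21 genes called. MEK/ERK output was higher (camera adjusted p = 9.85e-06; 0.351 with an estimated correlation; 0.0905 without Vhl A), with 0 of 22 genes called and 5 rising when adjusted over the list alone. Dusp5, a phosphatase gene induced by ERK, was 5 ± 1.64 and 15.93 ± 3.19 CPM. G2 and M phase was higher (camera adjusted p = 3.92e-10; 0.351 with an estimated correlation), all 22 genes having positive log2 changes and 1 rising when adjusted over the list alone. Cholesterol synthesis was lower (camera adjusted p = 0.000945; 0.373 with an estimated correlation), with 0 of 24 genes called. Cyp51 was 383.5 ± 31.2 and 236.7 ± 28.3 CPM. Astrocyte markers were lower (camera adjusted p = 0.0124; 0.265 with an estimated correlation, 0.0937 with a pseudocount of 0.1 in limma and 0.0985 without Vhl A), with 0 of 12 genes called and 2 falling when adjusted over the list alone. Those were Aqp4 (46.38 ± 5.33 and 15.88 ± 0.442 CPM) and Gja1 (437.3 ± 46.2 and 182.6 ± 28.6 CPM).

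In untreated cells 7 of 20 lists were thus called. Of 10 splits of these libraries into 3 and 3, the real split included, 6 called at least as many lists, so chance is not excluded for that number. The remaining lists did not pass. Camera gave adjusted p = 0.467 for HIF pathway components (median −0.22, mean 0.58), 0.465 for OPC identity, 0.18 for S phase, 0.126 for interferon, 0.228 for the unfolded protein response, 0.094 for p53, 0.309 for Wnt and 0.952 for Notch. It gave 0.113 for mitochondrially encoded genes, 0.952 for nuclear oxidative phosphorylation, 0.828 for neuron, 0.0977 for neural progenitor and 0.282 for mesenchymal markers. The oxidative phosphorylation list was lower in Vhl cells without Vhl A (camera adjusted p = 0.00197), opposite in sign to the result with all libraries. Dlx3, a homeobox gene, was 17.37 ± 12.1 CPM in Vhl cells and had 2 counts in all controls (ratio 377, 95% interval 104 to 3120; adjusted p = 0.0945, edgeR's quasi-likelihood test). Ascl2, a basic helix-loop-helix factor gene, was 0.104 ± 0.0299 and 6.82 ± 4.25 CPM (adjusted p = 0.0945, edgeR's quasi-likelihood test). At an unadjusted p under 0.05, 1267 of 13569 genes differed.

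The same comparison in DMSO asked what loss of VHL changed in the second experiment. Vegfa rose from 7.12 ± 1.02 to 102.6 ± 8.39 CPM (log2 3.84 ± 0.15, adjusted p = 2.11e-09, edgeR's quasi-likelihood test). Bnip3 rose from 19.79 ± 1.63 to 651.2 ± 30 CPM (log2 5.04 ± 0.06) and Slc2a1 from 58.51 ± 1.34 to 269.3 ± 2.75 CPM (log2 2.20 ± 0.04). Egln3, an oxygen-sensing hydroxylase gene that HIF itself induces, rose from 32.76 ± 1.99 to 121.1 ± 6.3 CPM. Hif1a mRNA fell from 330.8 ± 18 to 261.9 ± 9.17 CPM (log2 −0.34 ± 0.04). HIF1A is regulated mostly through protein stability, which RNA does not show. Sox10 fell from 51.31 ± 3.81 to 17.73 ± 2.4 CPM (log2 −1.53 ± 0.10, adjusted p = 2.4e-07, edgeR's quasi-likelihood test), whereas Olig2, the other main lineage factor gene, rose slightly from 1328 ± 43.8 to 1499 ± 14.5 CPM. Pdgfra, the OPC growth factor receptor gene, rose from 35.15 ± 7.61 to 64.09 ± 1.41 CPM.

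The largest rises by edgeR's log2 change, a ranking that favours genes near 0, were in genes with values near 0 in control cells. Dlx3 went from 3 counts in all 3 controls to 16.89 ± 0.959 CPM (ratio 251, 95% interval 85.4 to 1220) and Ascl2 from 0.221 ± 0.157 to 8.34 ± 0.477 CPM (log2 5.17 ± 0.59). Jakmip3 rose from 0.133 ± 0.065 to 16.12 ± 1.44 CPM, the collagen prolyl hydroxylase gene P4ha2 from 0.187 ± 0.21 to 11.1 ± 2.31 CPM and Tchh from 0.224 ± 0.154 to 8.73 ± 1.35 CPM. Cnnm1 rose from 0.0913 ± 0.0449 to 6.09 ± 1.18 CPM and the hexokinase gene Hk1 from 0.431 ± 0.331 to 26.5 ± 14.6 CPM. The values of Hk1, with 3793 counts over the 12 libraries, may not cover all reads of that gene. Loxl2, a lysyl oxidase gene, had no counts in controls and 35.38 ± 7.41 CPM in Vhl cells, at least 532-fold higher, although 48.6% of its 31-base words occur in another gene too. Among the largest falls, Erbb3, a neuregulin receptor gene, went from 9.04 ± 2.42 to 2.46 ± 0.46 CPM. Cdh19, a cadherin gene of glia and their precursors, fell from 6.71 ± 1.54 to 1.87 ± 0.482 CPM, and Luzp2, an OPC-enriched gene, from 6.44 ± 0.419 to 1.14 ± 0.191 CPM. Mcam fell from 5.46 ± 2 to 0.735 ± 0.857 CPM, the RNA-binding protein gene Igf2bp2 from 15.45 ± 7.3 to 2.34 ± 0.752 CPM and the mitochondrial RNA polymerase gene Polrmt from 5.97 ± 1.04 to 1.23 ± 0.349 CPM. Herc2 (16.18 ± 2.21 to 2.37 ± 2.07 CPM) and Phka1 (9.5 ± 1.7 to 1.97 ± 2.78 CPM) fell as well, but these calls were lost when single libraries were left out, and the values of Herc2 jump between libraries.

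Glycolysis rose with 15 of 18 genes up and none down (camera adjusted p = 2.91e-84). Pfkl rose from 104.8 ± 2.3 to 958.5 ± 3.66 CPM, Tpi1 from 377 ± 6.89 to 1889 ± 27.3 CPM and Pgam1 from 708.8 ± 22.1 to 2477 ± 57.1 CPM. The other hypoxia genes rose with 29 of 31 up (30 adjusted over the list alone; camera adjusted p = 2.6e-148). Examples were Egln1 (138.5 ± 4.8 to 751.6 ± 20.6 CPM), Mif (241.8 ± 3.12 to 1077 ± 33.8 CPM) and Fam162a (54.44 ± 1.42 to 403.7 ± 9.97 CPM). Of 9 HIF pathway components 2 rose, Egln1 and Egln3, and 3 fell. Camera put the list higher (adjusted p = 4.04e-07) although its median was −0.20 and its mean 0.17. With a pseudocount of 0.1 in limma the camera call ended (adjusted p = 0.919). Mitochondrially encoded genes fell in 11 of 13 cases (camera adjusted p = 5.74e-11; 0.0869 with an estimated correlation), mt-Co1 from 14770 ± 900 to 8968 ± 68.6 CPM. Nuclear genes of oxidative phosphorylation fell in 11 of 24 cases with 1 rise (camera adjusted p = 0.000117; 0.168 with an estimated correlation). Ndufa4, a cytochrome oxidase subunit gene, went from 313.2 ± 3.16 to 189.5 ± 7.48 CPM and Atp5b from 2652 ± 25.8 to 2084 ± 21.7 CPM. Fewer respiration and more glycolysis transcripts are a known pattern of HIF activity. Respiration was not measured, and HIF was not tested as the cause of the falls in mitochondrial genes.

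OPC identity genes rose in 12 of 20 cases and fell in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 2.86e-05). Examples were Tnr (35.57 ± 4.26 to 85.88 ± 8.15 CPM), Lhfpl3 (108.8 ± 7.75 to 200.7 ± 6 CPM) and C1ql1 (25.49 ± 1.76 to 49.82 ± 3.33 CPM). Oligodendrocyte maturation did not shift as a group, with 4 of 21 up and 4 down (camera adjusted p = 0.842). The connexin gene Gjc3 fell from 45.04 ± 2.14 to 17.67 ± 2.22 CPM and Car2 from 74.69 ± 4.78 to 54.71 ± 2.04 CPM, while Cnp rose from 130.3 ± 2.33 to 162.1 ± 6.02 CPM and Nkx6-2 from 2.99 ± 0.641 to 6.78 ± 1.43 CPM. Mbp, at 5.27 ± 1.16 and 3.96 ± 2.47 CPM, did not pass (adjusted p = 0.458), and neither did Myrf at 1.24 ± 0.659 and 0.948 ± 0.649 CPM (adjusted p = 0.693, edgeR's quasi-likelihood test for each). Neuron markers rose in 5 of 12 cases and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 9.31e-07). Dcx rose from 113 ± 3.72 to 269.6 ± 8.47 CPM and Elavl3 from 13.26 ± 0.613 to 46.85 ± 2.66 CPM. Astrocyte markers were mixed, with 4 of 12 up and 4 down (camera adjusted p = 0.218): Sox9 rose from 232.6 ± 0.934 to 435.5 ± 3.71 CPM and Gja1 fell from 229.3 ± 14.9 to 133.1 ± 3.92 CPM. Neural progenitor markers had 3 of 9 up and 2 down (camera adjusted p = 0.842) and mesenchymal markers 0 of 6 called (camera adjusted p = 0.842).

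Notch targets rose in 7 of 12 cases (camera adjusted p = 9.31e-07). Hes5, a Notch effector gene that holds back differentiation, rose from 14.5 ± 1.34 to 47.95 ± 1.98 CPM and Hey2 from 3.07 ± 0.487 to 10.2 ± 1.93 CPM. p53 targets rose in 9 of 16 cases and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00137; 0.0533 with an estimated correlation), led by the cell cycle inhibitor gene Cdkn1a from 165.4 ± 1.71 to 297.4 ± 6.79 CPM. G2 and M phase genes fell in 15 of 21 cases (camera adjusted p = 1.96e-06; 0.0871 with an estimated correlation). S phase genes fell in 12 of 24 (camera adjusted p = 0.0031; 0.229 with an estimated correlation). Plk1 fell from 190.3 ± 22.9 to 104.3 ± 5.14 CPM, Mcm2 from 392.9 ± 3.72 to 287.2 ± 25 CPM and Mki67 from 1012 ± 81.5 to 689.3 ± 37 CPM. The G2 and M list thus had opposite signs in the untreated and DMSO comparisons. Cholesterol synthesis fell in 13 of 24 cases (14 adjusted over the list alone; camera adjusted p = 0.000937; 0.195 with an estimated correlation), with Idi1 going from 341 ± 14.3 to 255.1 ± 7.28 CPM. MEK/ERK output rose in 9 of 21 cases (camera adjusted p = 0.0172; 0.0869 with an estimated correlation). Even so, Dusp6 (416.2 ± 9.52 and 384.9 ± 16.4 CPM), Spry4 (162.4 ± 3.12 and 177.8 ± 4.13 CPM) and Etv4 (226.1 ± 9.53 and 234.7 ± 9.69 CPM) did not pass. Unfolded protein response genes fell in 6 of 16 cases and rose in 2 (camera adjusted p = 0.0363), a call lost with an estimated correlation (0.44) or a pseudocount of 0.1 in limma (0.0782) and without control A (0.0731), control B (0.0501) or Vhl B (0.0575). The chaperone gene Hspa5 fell from 1256 ± 92.2 to 869 ± 74.7 CPM. Interferon genes rose in 3 of 14 cases (camera adjusted p = 0.322), among them H2-K1 from 2.34 ± 1.62 to 36.38 ± 2.6 CPM. Wnt targets rose in 2 of 9 cases with 1 fall (camera adjusted p = 0.297). Some lists were too small for a list test. Of the endothelial list, Flt1 rose from 0.729 ± 0.443 to 8.57 ± 0.083 CPM and Kdr from 3.29 ± 0.63 to 6.51 ± 0.666 CPM. Of the Schwann and neural crest list, Erbb3 fell while Pmp22 and Dhh did not pass, and of the pluripotency list Esrrb, Nanog and Fgf5 did not pass.

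In total 4343 of 13460 genes changed in DMSO by edgeR's quasi-likelihood test (1851 rose, 2492 fell), and at 2-fold or more 486 rose and 104 fell. The share of rises among calls, 42.6%, moved to 56.8% when libraries were scaled by total counts, so the excess of small falls depends on scaling. Mitochondrially encoded genes took 4.51% to 5.22% of the counts in control DMSO libraries and 3.18% to 3.29% in Vhl DMSO libraries.

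AZD8330 in control cells asked what blocking MEK changed with VHL present. Direct feedback genes of the ERK pathway fell: Dusp6, an ERK phosphatase gene, from 416.2 ± 9.52 to 20.93 ± 0.376 CPM (log2 −4.31 ± 0.05, adjusted p = 1.34e-14, edgeR's quasi-likelihood test). Spry4 fell from 162.4 ± 3.12 to 16.37 ± 2.34 CPM and Etv4 from 226.1 ± 9.53 to 15.93 ± 2.11 CPM. Ccnd1, the cyclin gene through which growth factors drive entry into the cell cycle, fell from 694.8 ± 13.6 to 152.9 ± 3.17 CPM and Mki67 from 1012 ± 81.5 to 128.7 ± 10.6 CPM. Differentiation genes rose: Gpr17, which marks OPCs committed to become oligodendrocytes, from 56.14 ± 1.27 to 509.5 ± 5.49 CPM and Sox10 from 51.31 ± 3.81 to 97.54 ± 2.48 CPM (log2 0.93 ± 0.09). The astrocyte filament gene Gfap rose from 4.13 ± 0.526 to 131.2 ± 7.81 CPM (log2 4.99 ± 0.12). Myrf rose from 1.24 ± 0.659 to 4.34 ± 1.65 CPM (adjusted p = 0.0144, edgeR's quasi-likelihood test), a call lost without control DMSO A or control AZD8330 C.

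MEK/ERK output fell in 14 of 21 cases and rose in 4 (camera adjusted p = 2.79e-15). S phase fell in 23 of 24 cases (camera adjusted p = 6.41e-15), such as Mcm5 from 371 ± 14.4 to 53.92 ± 1.28 CPM. G2 and M phase fell in 21 of 21 cases (camera adjusted p = 2.25e-28), such as Top2a from 1033 ± 86.2 to 135.6 ± 5.09 CPM. Oligodendrocyte maturation rose in 15 of 21 cases (camera adjusted p = 6.97e-10), including Cnp from 130.3 ± 2.33 to 395.6 ± 14.9 CPM and Gjc3 from 45.04 ± 2.14 to 199.8 ± 0.579 CPM. OPC identity rose in 12 of 20 cases and fell in 4 (camera adjusted p = 0.000112). Astrocyte markers rose in 9 of 12 and fell in 1 (camera adjusted p = 5.34e-09). Notch targets rose in 11 of 12 cases (camera adjusted p = 5.48e-08) and neural progenitor markers in 6 of 9 with 1 fall (camera adjusted p = 0.00888). Examples are Tnr from 35.57 ± 4.26 to 195.1 ± 4.58 CPM, Aqp4 from 3.32 ± 0.387 to 48.03 ± 1.54 CPM, Hes5 from 14.5 ± 1.34 to 132 ± 9.27 CPM and Sox3 from 173.4 ± 7.68 to 455.2 ± 24 CPM. Cholesterol synthesis fell in 20 of 24 cases (camera adjusted p = 9.19e-06; 0.102 with an estimated correlation). p53 targets fell in 9 of 16 cases and rose in 4 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0404; 0.125 with an estimated correlation, 0.12 with a pseudocount of 0.1 in limma and 0.0516 without control DMSO C). Gtse1, itself a G2 phase gene, went from 145.8 ± 1.9 to 17.63 ± 2.2 CPM.

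Hypoxia and glycolysis genes did not shift as groups in control cells. Glycolysis had 3 of 18 up and 7 down (camera adjusted p = 0.459; median −0.23, mean 0.05). The other hypoxia genes had 9 of 31 up and 10 down (camera adjusted p = 0.794), with Ddit4 rising from 96.6 ± 8.11 to 357 ± 38 CPM and Egln1 falling from 138.5 ± 4.8 to 81.9 ± 1.39 CPM. Vegfa, at 7.12 ± 1.02 and 5.97 ± 1.01 CPM, did not pass (adjusted p = 0.298, edgeR's quasi-likelihood test). Camera gave adjusted p = 0.893 for HIF components, 0.159 for interferon (8 of 14 up, 9 adjusted over the list alone), 0.863 for the unfolded protein response and 0.465 for Wnt. It gave 0.896 for mitochondrially encoded genes, 0.0543 for oxidative phosphorylation (14 of 24 down, 1 up), 0.0543 for neuron markers (6 of 12 up, 3 down) and 0.324 for mesenchymal markers (4 of 6 up, 1 down).

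The largest falls included Tmem173, which encodes the innate immune sensor STING, from 47.15 ± 3.82 to 1.27 ± 0.216 CPM and Hs3st2 from 19.02 ± 0.946 to 0.816 ± 0.187 CPM. Prokr1 fell from 5.25 ± 0.641 to 0.178 ± 0.135 CPM, Gcnt4 from 11.72 ± 2.28 to 0.595 ± 0.143 CPM and Rapgef4 from 14.58 ± 0.461 to 0.839 ± 0.208 CPM. The mitotic genes Ttk (13.15 ± 1.49 to 0.555 ± 0.609 CPM) and Pttg1 (17.95 ± 6.47 to 1.05 ± 0.571 CPM) were among them too. The largest rises included, besides Gfap, Capn1 (0.414 ± 0.324 to 22.17 ± 3.1 CPM), the desaturase gene Scd4 (0.11 ± 0.0702 to 6.17 ± 0.35 CPM), Adamtsl4 (0.252 ± 0.164 to 7.61 ± 0.567 CPM) and Itih3 (0.22 ± 0.223 to 7.08 ± 1.06 CPM). Galnt14 (2 counts in DMSO, ratio 116, 95% interval 31.7 to 960) and Hk1 (0.431 ± 0.331 to 13.59 ± 9.27 CPM) were among them too. The values of Hk1 may not cover all reads of that gene. Of the lists too small for a test, Esrrb fell from 18.98 ± 2.72 to 3.52 ± 1.09 CPM and Pmp22 from 80.94 ± 1.54 to 24.41 ± 3.44 CPM. Arsg rose from 0.254 ± 0.214 to 7.69 ± 7.06 CPM, but its values jump between libraries. In total 8183 of 13460 genes changed by edgeR's quasi-likelihood test (3912 rose, 4271 fell), and at 2-fold or more 1419 rose and 1296 fell. The share of rises, 47.8%, was 52.2% with total-count scaling.

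**Figure D2:**
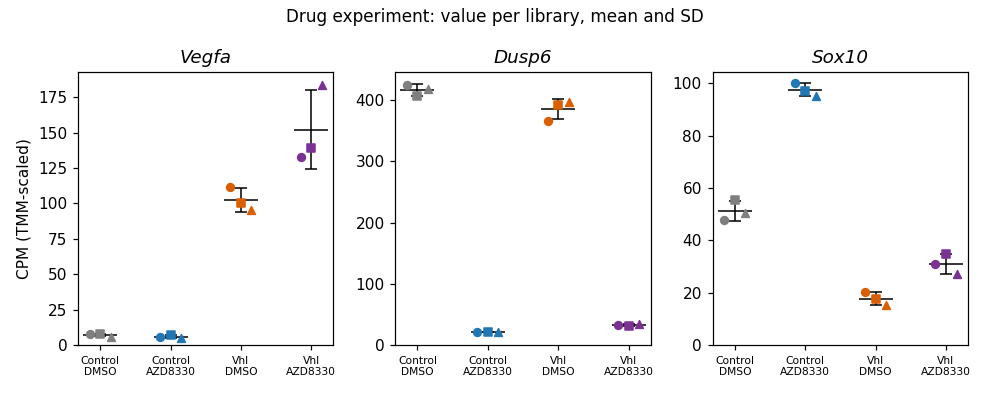
Vegfa, Dusp6 and Sox10 in CPM (vertical axes) per library of control and Vhl cells in DMSO or AZD8330, with circles for A, squares for B and triangles for C. Bars show mean and SD; Sox10 is higher with the drug in each genotype and lower in Vhl than in control cells.

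AZD8330 in Vhl cells asked whether the drug acted the same way after loss of VHL. Dusp6 fell from 384.9 ± 16.4 to 32.85 ± 2.16 CPM (log2 −3.55 ± 0.05, adjusted p = 5.25e-14, edgeR's quasi-likelihood test). Etv4 fell from 234.7 ± 9.69 to 24.77 ± 1.46 CPM, Ccnd1 from 887.2 ± 18.2 to 237.4 ± 5.13 CPM and Mki67 from 689.3 ± 37 to 56.4 ± 4.32 CPM. Gpr17 rose from 59.62 ± 3.29 to 527.2 ± 13.8 CPM, Gfap from 2.88 ± 0.456 to 95.42 ± 11.6 CPM and Sox10 from 17.73 ± 2.4 to 31.05 ± 3.76 CPM (log2 0.81 ± 0.11). Vegfa rose further from 102.6 ± 8.39 to 152 ± 27.9 CPM (log2 0.57 ± 0.12, adjusted p = 0.00125, edgeR's quasi-likelihood test) and Bnip3 from 651.2 ± 30 to 947.1 ± 33.5 CPM. Slc2a1 rose from 269.3 ± 2.75 to 295 ± 9.72 CPM (adjusted p = 0.00463, edgeR's quasi-likelihood test), a call lost with no filter on low values and without Vhl AZD8330 A or B.

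MEK/ERK output fell in 12 of 21 cases and rose in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 4.9e-18). S phase fell in 24 of 24 cases (camera adjusted p = 1.15e-22) and G2 and M phase in 21 of 21 (camera adjusted p = 3.12e-49). p53 targets fell in 10 of 16 cases and rose in 3 (camera adjusted p = 0.00107). Oligodendrocyte maturation rose in 12 of 21 cases (13 adjusted over the list alone; camera adjusted p = 1.33e-09) and OPC identity in 12 of 20 with 3 falls (camera adjusted p = 0.000301). Astrocyte markers rose in 9 of 12 cases with 1 fall (camera adjusted p = 2.26e-09) and Notch targets in 9 of 12 with 1 fall (10 and 2 adjusted over the list alone; camera adjusted p = 8.15e-06). Neural progenitor markers rose in 6 of 9 cases with 1 fall (camera adjusted p = 0.00654; median 0.30, mean −0.15). The hypoxia genes other than glycolysis rose in 19 of 31 cases (20 adjusted over the list alone; camera adjusted p = 0.00624; 0.0827 with an estimated correlation). Ddit4 rose from 269.9 ± 11.8 to 614.9 ± 43.3 CPM and Gbe1 from 198.1 ± 5.2 to 314.8 ± 14.3 CPM. Cholesterol synthesis had 14 of 24 up and 2 down and did not pass as a group (camera adjusted p = 0.0668). Hmgcs1 rose from 1494 ± 61.2 to 2670 ± 130 CPM.

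Not passing in that comparison were glycolysis (8 of 18 up, 1 down; camera adjusted p = 0.178), HIF components (4 of 9 up; 0.21), interferon (9 of 14 up; 0.0668), the unfolded protein response (3 of 16 up, 7 down; 0.267) and Wnt (3 of 9 up, 3 down; 0.743; median −0.47, mean 0.41). The same camera test gave adjusted p = 0.0853 for mitochondrially encoded genes (9 of 13 down), 0.0668 for oxidative phosphorylation (2 of 24 up, 14 down), 0.0804 for neuron markers (4 of 12 up, 2 down) and 0.0631 for mesenchymal markers (5 of 6 up, 1 down). The largest rises included Klf2, a transcription factor gene, from 2.16 ± 0.493 to 87.32 ± 5.21 CPM, Pi15 from 0.0984 ± 0.116 to 7.55 ± 0.75 CPM and Bbox1 from 0.114 ± 0.197 to 6.05 ± 1.51 CPM. Also among them were Scd4 from 0.139 ± 0.179 to 8.36 ± 0.664 CPM, Capn1 from 0.374 ± 0.0927 to 14.62 ± 1.75 CPM, Galnt14 from 0.213 ± 0.369 to 6.66 ± 2.03 CPM and Cyp3a13 (2 counts in DMSO, ratio 191, 95% interval 52.6 to 1580). The largest falls included Tmem173 from 32.28 ± 0.987 to 1.17 ± 0.137 CPM and the DNA replication genes Cdc6 (24.06 ± 8.24 to 1.11 ± 1.02 CPM) and Pif1 (23.45 ± 1.64 to 0.905 ± 0.843 CPM). Ttk (7.32 ± 2.37 to 0.18 ± 0.199 CPM), Igfbp4 (22.27 ± 4.05 to 1.28 ± 1.15 CPM) and Gcnt4 (10.12 ± 1.05 to 0.604 ± 0.265 CPM) were among them too. Dgkk (7.76 ± 6.12 CPM to no counts, at least 108-fold lower) and E2f8 (24.01 ± 2.72 to 0.284 ± 0.492 CPM) fell as well, but their values jump between libraries. In total 6924 of 13460 genes changed by edgeR's quasi-likelihood test (3479 rose, 3445 fell), and at 2-fold or more 983 rose and 837 fell. The share of rises, 50.2%, was 49.4% with total-count scaling.

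Vhl against control cells in AZD8330 asked which effects of VHL loss remained under the drug. Vegfa rose from 5.97 ± 1.01 to 152 ± 27.9 CPM (log2 4.67 ± 0.16, adjusted p = 2.9e-10, edgeR's quasi-likelihood test). Bnip3 rose from 37.21 ± 0.566 to 947.1 ± 33.5 CPM, Slc2a1 from 51.3 ± 1.23 to 295 ± 9.72 CPM and Egln3 from 26.1 ± 0.623 to 171.2 ± 5.01 CPM. Sox10 fell from 97.54 ± 2.48 to 31.05 ± 3.76 CPM (log2 −1.65 ± 0.10, adjusted p = 4.47e-08, edgeR's quasi-likelihood test). Dusp6 was higher in Vhl cells under the drug, at 32.85 ± 2.16 against 20.93 ± 0.376 CPM, as was Myc, at 158.1 ± 1.73 against 85.17 ± 3.28 CPM, and Ccnd1, at 237.4 ± 5.13 against 152.9 ± 3.17 CPM, all of which rose. Mki67 fell from 128.7 ± 10.6 to 56.4 ± 4.32 CPM.

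Glycolysis rose in 15 of 18 cases (camera adjusted p = 4.39e-99) and the other hypoxia genes in 29 of 31 (30 adjusted over the list alone; camera adjusted p = 3.45e-157), Gbe1 from 25.52 ± 1.22 to 314.8 ± 14.3 CPM. HIF components had 2 of 9 up and 3 down (camera adjusted p = 1.83e-09; median 0.02, mean 0.58), a call that ended with a pseudocount of 0.1 in limma (adjusted p = 0.655). Cholesterol synthesis rose in 22 of 24 cases (camera adjusted p = 1.9e-17), Lss from 131.4 ± 7.28 to 309.6 ± 24 CPM. Oligodendrocyte maturation fell in 8 of 21 cases and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0242; 0.1 with an estimated correlation). Gjc3 fell from 199.8 ± 0.579 to 109.3 ± 5.66 CPM and Zfp488, a regulator of differentiation, from 17.28 ± 0.525 to 8.51 ± 0.407 CPM. OPC identity rose in 11 of 20 cases and fell in 3 (12 and 4 adjusted over the list alone; camera adjusted p = 0.0318), a call lost with an estimated correlation (0.079), median-of-ratios scaling (0.0767) or a pseudocount of 0.1 in limma (0.0554) and without any of 5 single libraries (0.0699 to 0.0938). Cacng4 rose from 94.39 ± 3.88 to 192.3 ± 4.22 CPM. MEK/ERK output rose in 13 of 21 cases and fell in 1 (15 and 2 adjusted over the list alone; camera adjusted p = 4.41e-05).

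Mitochondrially encoded genes fell in 13 of 13 cases (camera adjusted p = 1.63e-19) and oxidative phosphorylation in 10 of 24 with 2 rises (camera adjusted p = 0.00717; 0.287 with an estimated correlation). G2 and M phase fell in 17 of 21 cases (18 adjusted over the list alone; camera adjusted p = 4.09e-12). S phase fell in 13 of 24 cases (15 adjusted over the list alone; camera adjusted p = 0.00139; 0.211 with an estimated correlation). The unfolded protein response fell in 7 of 16 cases with 1 rise (camera adjusted p = 0.00207; 0.283 with an estimated correlation). Neuron markers rose in 9 of 12 cases and fell in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.000835), Elavl3 from 22.37 ± 0.62 to 67.47 ± 2.38 CPM. Camera gave adjusted p = 0.317 for interferon (5 of 14 up, 1 down), 0.0732 for p53 (5 of 16 up, 2 down), 0.241 for Notch (6 of 12 up, 3 down) and 0.921 for Wnt (1 of 9 up, 2 down; median 0.15, tested direction lower). It gave 0.581 for astrocyte (4 of 12 up, 5 down), 0.564 for neural progenitor (3 of 9 up, 3 down) and 0.241 for mesenchymal markers (3 of 6 up).

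Dlx3 (2 counts in control cells, ratio 415, 95% interval 115 to 3430), Loxl2 (0.216 ± 0.374 to 69.36 ± 6.39 CPM), Jakmip3 (0.269 ± 0.176 to 24.43 ± 3.27 CPM) and Tchh (0.216 ± 0.199 to 10.02 ± 0.952 CPM) were again among the largest rises. So were the hormone receptor gene Gipr (0.29 ± 0.101 to 12.9 ± 5.14 CPM) and Mgarp (no counts to 5.3 ± 1.54 CPM, at least 79-fold). Hecw2 rose from 0.086 ± 0.0745 to 7.48 ± 5.74 CPM, but its values jump between libraries. The largest falls included Luzp2 (27.45 ± 0.485 to 5 ± 0.134 CPM), Erbb3 (16.4 ± 1.25 to 3.85 ± 0.17 CPM), and Tmem132b (120.4 ± 11.7 to 25.2 ± 2.03 CPM). Others were Capn6 (17.05 ± 0.718 to 2.31 ± 0.438 CPM), the retinoic acid synthesis gene Aldh1a1 (100.4 ± 4.45 to 26.89 ± 0.59 CPM), Gem (5.19 ± 0.457 to 1.07 ± 0.439 CPM) and Cacng5 (5.14 ± 0.964 to 1.19 ± 0.11 CPM). Cct8 fell from 34.16 ± 4.97 to 5.32 ± 5.51 CPM, a call lost without Vhl AZD8330 B or C. In total 4033 of 13460 genes changed by edgeR's quasi-likelihood test (2149 rose, 1884 fell), and at 2-fold or more 502 rose and 218 fell. The share of rises, 53.3%, moved to 43.7% with median-of-ratios scaling and to 45.5% with quantile normalization, so the excess of rises depends on scaling.

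The difference of drug effects asked for genes on which AZD8330 acted otherwise in Vhl than in control cells. Cholesterol synthesis stood out, with 21 of 24 genes higher in the difference and 0 lower (median log2 1.08; camera adjusted p = 1.8e-69). Idi1 changed by log2 −1.13 with the drug in control cells and 0.46 in Vhl cells (difference 1.59 ± 0.08, adjusted p = 3.7e-07, edgeR's quasi-likelihood test). Lss changed by −0.95 and 0.53 (difference 1.48 ± 0.09) and Hmgcs1 by −0.25 and 0.84 (difference 1.08). The differences of Ebp, Pmvk and Hsd17b7 did not pass.

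**Figure D3:**
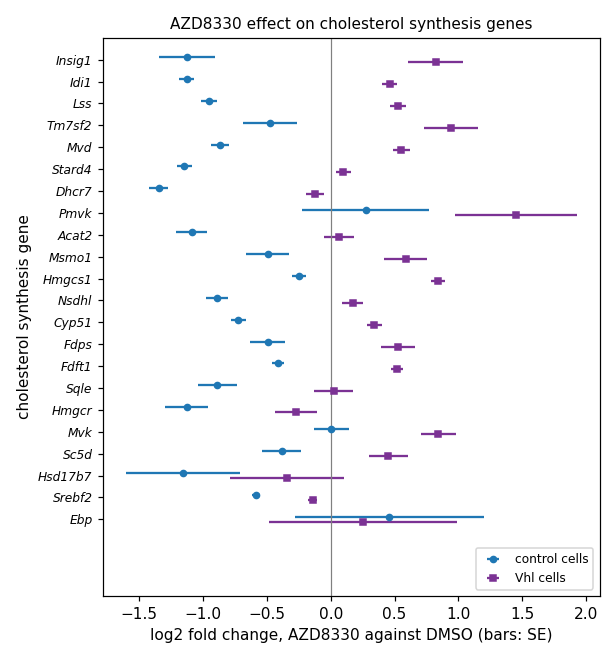
Log2 change with AZD8330 against DMSO (horizontal axis, bars SE) in control cells (circles) and Vhl cells (squares). 22 of the 24 tested cholesterol synthesis genes are drawn, and the rest are not shown. Most genes lie left of 0 in control cells and right of 0 or near it in Vhl cells.

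Hypoxia-related lists were higher in the difference. Glycolysis had 7 of 18 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 2.95e-08), and the other hypoxia genes had 11 of 31 higher and 3 lower (12 and 3 adjusted over the list alone; camera adjusted p = 4.08e-06). HIF components had 3 of 9 higher and 1 lower (camera adjusted p = 0.0167; 0.0595 with an estimated correlation; 0.178 with a pseudocount of 0.1 in limma; 0.0511 without control AZD8330 B). Egln3 (0.83 ± 0.08), Slc2a1 (0.32 ± 0.05) and Vegfa (0.82 ± 0.23, adjusted p = 0.0373, edgeR's quasi-likelihood test, lost in several alternatives) were higher and Bnip3 (−0.37 ± 0.08) lower. MEK/ERK output was suppressed less in Vhl cells, with 6 of 21 higher and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.000408), including Dusp6 (0.76 ± 0.07), Myc (0.81 ± 0.05), Etv4 (0.59 ± 0.11) and Ccnd1 (0.28 ± 0.04). G2 and M phase was lowered more, with 7 of 21 lower (13 adjusted over the list alone; camera adjusted p = 2.95e-08; 0.0595 with an estimated correlation), and Mki67 with it (−0.64 ± 0.11).

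Notch targets gained less from the drug in Vhl cells, with 6 of 12 lower (8 adjusted over the list alone; camera adjusted p = 8.52e-08), Hes5 by −1.34 ± 0.10. Oligodendrocyte maturation had 6 of 21 lower and 1 higher (camera adjusted p = 0.00868; 0.0595 with an estimated correlation), with Cnp lower by −0.44 ± 0.06. OPC identity had 5 of 20 lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.0262; 0.0595 with an estimated correlation). Mitochondrially encoded genes had 6 of 13 lower (8 adjusted over the list alone; camera adjusted p = 2.48e-05; 0.21 with an estimated correlation). Astrocyte markers had 3 of 12 lower (camera adjusted p = 0.0381; 0.0963 with an estimated correlation), a call lost without control DMSO A, control AZD8330 A or Vhl DMSO A. Sox10 (−0.12 ± 0.14, adjusted p = 0.669) and Pdgfra (−0.13 ± 0.17, adjusted p = 0.705) did not differ in edgeR's quasi-likelihood test. Vhl itself was lower by −0.27 ± 0.07 (adjusted p = 0.0242, edgeR's quasi-likelihood test), a call lost without control DMSO C, control AZD8330 A or Vhl DMSO B or C. Camera gave adjusted p = 0.159 for S phase, 0.999 for interferon, 0.117 for the unfolded protein response, 0.159 for p53 and 0.124 for Wnt. It gave 0.262 for oxidative phosphorylation, 0.0892 for neuron, 0.223 for neural progenitor and 0.152 for mesenchymal markers.

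The largest differences upward were Cyp3a13 (3.55 ± 0.71), Trp53 (2.69 ± 0.31), Prokr1 (2.69 ± 0.66), Npas1 (2.56 ± 0.52) and Sertm1 (2.28 ± 0.40). Those downward were Wdr41 (−9.68 ± 2.81), Hk1 (−4.08 ± 0.97), Fmnl1 (−2.99 ± 0.79), Phyhd1 (−2.02 ± 0.53) and Vwa5b1 (−1.999 ± 0.61). The values of Wdr41 jump between libraries, and those of Trp53, with 11245 counts over the 12 libraries, and Hk1, with 3793, may not cover all reads of these genes. The calls on Prokr1, Fmnl1 and Phyhd1 were lost without some single libraries. The call on Hk1 was lost in limma with pseudocount 1 or quantile normalization and without control DMSO B. The calls on Wdr41 and Vwa5b1 were lost in limma and without most single libraries, and Vwa5b1 was at −0.12 in limma with pseudocount 1. In total 1718 of 13460 genes differed by edgeR's quasi-likelihood test (1051 higher, 667 lower), and at 2-fold or more 95 were higher and 77 lower. The share that was higher, 61.2%, fell to 43.8% with total-count scaling and to 46.1% with quantile normalization. The balance also turned with a minimum of 5 CPM (669 higher, 1037 lower). It turned without control AZD8330 B (465 and 781) or C or any Vhl AZD8330 library, and held without any other single library.

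Vhl cells in AZD8330 were also compared with control cells in DMSO, a comparison added after the data were seen, to ask whether the drug brought Vhl cells back to the level of control cells without it. Sox10 stayed lower (31.05 ± 3.76 against 51.31 ± 3.81 CPM, log2 −0.72 ± 0.10, adjusted p = 2.54e-05, edgeR's quasi-likelihood test). Gpr17 rose (527.2 ± 13.8 against 56.14 ± 1.27 CPM), and oligodendrocyte maturation rose in 15 of 21 cases with 1 fall (camera adjusted p = 2.86e-06). Cholesterol synthesis was near the control level, with 8 of 24 up and 4 down (camera adjusted p = 0.95). Glycolysis stayed higher in 17 of 18 cases (camera adjusted p = 2.67e-22) and the other hypoxia genes in 30 of 31 (camera adjusted p = 3.04e-41). G2 and M phase fell in 21 of 21 cases (camera adjusted p = 2.03e-38). Astrocyte markers rose in 9 of 12 cases with 1 fall (camera adjusted p = 1.08e-07). In total 8430 genes changed by edgeR's quasi-likelihood test (4265 rose, 4165 fell).

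Relations across genes were computed 3 times between comparisons, always with no library in common; genes are not independent replicates, so these carry no p-value. The drug effects in control and Vhl cells had a Spearman correlation of 0.826, with 2941 genes up in each against 1011 expected from the separate counts and 3140 down against 1093 expected. The effects of VHL loss in DMSO and AZD8330 had a correlation of 0.484, with 1117 up in each against 295.5 expected and 1124 down against 348.8 expected. The effects of VHL loss in untreated and DMSO cells had a correlation of 0.156 over 12913 genes, and 59.9% of the genes called in DMSO had the same sign in untreated cells. The 2 genes called in untreated cells, Mif and Fam162a, rose in DMSO too, and 0 of them moved the opposite way with AZD8330 in Vhl cells. Without Vhl A, 307 of the 439 untreated calls were called in DMSO with the same sign. No expected number was computed for this overlap, and 32.3% of all tested genes were called in DMSO in either direction. The 439 calls also come from the run that left out the library with the weak response.

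Positions of the genes followed in the figures, on GRCm38 with GENCODE M21, are Vegfa on chromosome 17 from 46016993 to 46032369, Slc2a1 on chromosome 4 from 119108711 to 119137983, Bnip3 on chromosome 7 from 138890836 to 138909519. Sox10 lies on chromosome 15 from 79154908 to 79165240 and Dusp6 on chromosome 10 from 99263231 to 99267489.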

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

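Several tests below were chosen after the result was seen. These are the 3 tests of the Vhl A library and the test of values that are not whole. The other tests were set down before their values were seen.

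The first set of unusual results comes from the test of whether AZD8330 acted differently in Vhl and control cells. It picked out 1718 genes by edgeR's quasi-likelihood test. Upward log2 differences were 3.545 for Cyp3a13, 2.693 for Trp53, 2.69 for Prokr1, 2.562 for Npas1 and 2.277 for Sertm1. Downward ones were −9.682 for Wdr41, −4.084 for Hk1, −2.987 for Fmnl1, −2.021 for Phyhd1 and −1.999 for Vwa5b1. The calls on Prokr1, Fmnl1 and Phyhd1 were lost without some single libraries and that on Hk1 in limma with pseudocount 1. Those on Wdr41 and Vwa5b1 were lost in limma and without most single libraries, and Vwa5b1 was at −0.1154 in limma with pseudocount 1. Of the genes fixed beforehand, Vegfa differed by 0.8221, Egln3 by 0.8296, Slc2a1 by 0.3221, Dusp6 by 0.7616, Etv4 by 0.5862 and Ccnd1 by 0.2814. Vhl differed by −0.2661, Bnip3 by −0.3734 and Mki67 by −0.6377. The calls on Vegfa and Vhl were lost without some single libraries. Lists called higher had median differences of 1.08 for cholesterol synthesis, 0.761 for HIF components, 0.439 for glycolysis, 0.295 for MEK/ERK output and 0.233 for other hypoxia genes. Lists called lower had −0.522 for G2 and M phase, −0.335 for oligodendrocyte maturation, −0.236 for mitochondrially encoded genes, −0.197 for Notch targets, −0.12 for OPC identity and −0.088 for astrocyte markers. With an estimated correlation 6 of these 11 calls ended (camera adjusted p = 0.0595 for HIF components, G2 and M phase, oligodendrocyte maturation and OPC identity, 0.21 for mitochondrially encoded genes and 0.0963 for astrocyte markers). HIF components also ended with a pseudocount of 0.1 in limma (camera adjusted p = 0.178) and without control AZD8330 B (0.0511), and astrocyte markers without any of 3 single libraries.

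The other unusual result lies in columns that no comparison used. The authors' own mean columns give a ratio of 3.218 between Vhl and control for Vegfa, whereas the means of the 3 libraries per group give 51.76. In all rows their Vhl column equals the mean of control B, control C and Vhl A within 0.01, and it differs from the mean of the 3 Vhl libraries in 26229 rows. For Bnip3 the ratios are 4.793 and 23.2.

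The first pattern is the weak response of the untreated Vhl A library, which over 37 hypoxia and glycolysis genes reached a median share of 0.169 of the response of Vhl B and C. An admixture of unedited cells alone would give a similar share for all genes. The quartiles of 0.0816 and 0.264 lie a ratio of 3.24 apart, against 1.71 between B and C. Fam162a reached 1.01 and Mif 0.834, the 2 genes called in untreated cells, while Vegfa reached 0.0613. The same spread gives a wider ratio around a low share, and the quartiles of B over C were 0.758 and 1.3. Vhl A also differed from B and C in Sox10 (327.1 against 15.32 and 16.02 CPM). Admixture together with another difference of the culture is therefore not excluded. Low depth is argued against because Vhl A was the deepest untreated library (21.16e6 counts). A swap with a control library is argued against because no control library exceeded the others by more than a median log2 of 0.0603 over the hypoxia list. A culture earlier or weaker in its response stays open; no other sample tests it.

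The second pattern is the difference of drug effects on cholesterol synthesis. Scaling is argued against, because the median difference over all genes stayed within 0.0344 under any scaling while the median of the list stayed between 1.02 and 1.08. Values that cover only part of a gene are argued against as the whole cause, because the 5 of 24 members with 1 to 3 annotated transcripts had a median difference of 1.31. A change in how MEK signalling feeds into sterol control after loss of VHL stays open. So does a difference in culture conditions such as cell density, and these samples do not separate the explanations.

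The third pattern is the 104 genes whose estimated counts lie over 10 times apart between libraries of a group, against 10489 other genes with at least 100 counts. Shared sequence is argued against: the median share of words found in another gene was 0.523%, against 0.433% in the others. Values that cover only part of a gene's transcripts stay open, since 9.62% of these genes have a single annotated transcript against 11.4% of the others. Transcript estimates that were not summed stay open too, since 57.9% of values were not whole among unshared genes with at least 5 transcripts, and 19.1% among those with a single transcript. The calls on Herc2, Arsg, Dgkk, E2f8, Hecw2 and Wdr41 rest on such values.

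Other splits of the libraries into 3 and 3 were run for each comparison. 10 splits are too few for a share under 0.05, so they cannot exclude chance, and the values are given. Counted among them with at least the real number of calls, the real split included, genes gave 1 of 10 in each of the 5 comparisons of 2 groups. The real numbers and the highest of the other splits were 2 and 1 for untreated cells, 4343 and 1 for Vhl in DMSO, 8183 and 0 for AZD8330 in control cells, 6924 and 0 in Vhl cells, and 4033 and 1 for Vhl in AZD8330. Lists gave 6 of 10 in untreated cells (7 and 10), 1 in DMSO (14 and 12), 4 for AZD8330 in control cells (10 and 10), 1 in Vhl cells (10 and 9) and 1 for Vhl in AZD8330 (13 and 8). The numbers of lists called in untreated cells and for AZD8330 in control cells were thus reached by other splits as well. For the difference 100 splits were drawn. Genes gave 2 of 100 (1718 and 5324), and the split with 5324 exchanged the genotype labels within a treatment, so it carries the genotype effect. Lists gave 11 of 100 (11 and 14), so chance is not excluded for the number of lists.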

How the results depend on the processing

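Limits come first. The labels do not say that replicates are separate cultures. The 3 libraries per group spread widely in the untreated set. For some genes the values may not cover all reads. The count of untreated calls was 2 in edgeR and 4 in limma with pseudocount 1 or 0.1, 6 with quantile normalization, 143 without a filter (28714 genes tested) and 355 in DESeq2. Leaving out single libraries gave 0 to 439 calls, with 439 without Vhl A and 0 without control A, B or C or Vhl B. At an unadjusted p under 0.05, 1267 genes differed with all libraries. Why the tools differ was not tested. Limma with pseudocount 1, DESeq2 and the fit without the 2 untreated A libraries were added after the data were seen. That last fit gave 606 calls, but its libraries were left out because of their values, so its p-values are not evidence. Of the untreated calls, 2 repeated in DMSO with the same sign. The alternatives gave 4 in limma with either pseudocount, 6 with quantile normalization, 112 without a filter, 212 in DESeq2, 375 without the A libraries and 0 to 307 when single libraries were left out. Calls that moved the opposite way with AZD8330 in Vhl cells numbered 0, against 1 with quantile normalization, 46 without a filter, 162 in DESeq2, 270 without the A libraries and 0 to 129 when single libraries were left out. These counts leave out genes that moved the same way: of the calls without the A libraries, 120 of the higher ones rose and 116 fell with the drug, and 154 of the lower ones rose and 25 fell. AZD8330 changed 6924 of 13460 genes in Vhl cells. With an estimated correlation the number of lists called went from 7 to 0 in untreated cells, from 14 to 6 in DMSO, from 13 to 8 in AZD8330 and from 11 to 5 for the difference. Leaving out single libraries gave 7 to 11 lists in untreated cells. The oxidative phosphorylation list in untreated cells was not called (camera adjusted p = 0.952), but was lower in Vhl cells without Vhl A (0.00197) and without the A libraries (0.000497). Leaving out other libraries gave up to 0.832. In the drug experiment leaving out single libraries gave 3625 to 3962 calls in DMSO, of which 3478 to 3721 were also calls of the main fit. For AZD8330 it gave 7615 to 7787 in control cells (7452 to 7562 shared) and 6341 to 6471 in Vhl cells (6061 to 6248 shared). It gave 3436 to 3721 for Vhl in AZD8330 (3239 to 3313 shared) and 1238 to 1584 for the difference (1075 to 1438 shared). No named gene changed direction where it passed in the main fit or in the alternative. Genes that passed in neither did change sign, such as Sox10 and Myrf in untreated cells (log2 −0.97 and −1.81 with all libraries, 0.44 and 0.42 without control A). Without both A libraries they were at −2.49 and 0.48.

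With the letter as a replicate block, 0 genes were called in untreated cells and 0 repeated in DMSO. Of the list results 118 stayed and 2 became stronger. The labels do not link samples of the same letter, and correlations of same-letter residuals were −0.0481 to 0.0451 in the untreated set and −0.0341 to 0.0493 in the drug experiment.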

Other observations

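The sign of the G2 and M phase list differed between the experiments. In untreated cells 22 of 22 G2 and M phase genes had positive log2 changes in Vhl cells, while in DMSO 15 of 21 fell and none rose. Tpx2 was 90.74 ± 31.7 CPM in untreated control and 157.9 ± 25.2 CPM in untreated Vhl cells, whereas Plk1 fell in DMSO from 190.3 ± 22.9 to 104.3 ± 5.14 CPM. Mki67 was 440.3 ± 296 and 693.3 ± 282 CPM in untreated cells and fell from 1012 ± 81.5 to 689.3 ± 37 CPM in DMSO. The experiments were tested separately, and both list calls end with an estimated correlation (camera adjusted p = 0.351 in untreated cells and 0.0871 in DMSO).

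Genes of differentiation that rose with AZD8330 did so to different ends in Vhl cells. Gpr17 reached 527.2 ± 13.8 CPM, near its level in drug-treated control cells (509.5 ± 5.49 CPM). Sox10 gained a similar log2 in control (0.93 ± 0.09) and Vhl cells (0.81 ± 0.11), so its level in Vhl cells with the drug stayed under that of control cells in DMSO. Among astrocyte markers Gja1 rose from 133.1 ± 3.92 to 418.4 ± 16.3 CPM in Vhl cells and from 229.3 ± 14.9 to 903.4 ± 20.7 CPM in control cells.

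A hypothesis is that low Sox10 limits part of the oligodendrocyte maturation list but not Gpr17 when MEK is blocked. Restoring Sox10 in Vhl cells and measuring that list with AZD8330 would test it. A hypothesis is that sterol synthesis in Vhl cells no longer depends on MEK, since the median difference of the list was 1.08 and that of its members with few transcripts 1.31. Measuring nuclear SREBP2 in the 4 groups would test it. A hypothesis is that the untreated Vhl A culture had a weaker HIF response in most genes, since its median share of the response of Vhl B and C was 0.169, although Fam162a reached 1.01 and Mif 0.834. Measuring HIF1A protein in replicate cultures would test it.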
